A study of Mus musculus with 8 samples.

How the data were processed

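Total RNA was isolated from powdered frozen dorsal skin, and biotin-labelled RNA was hybridised to 1-colour mouse arrays, per the labels' protocols. The labels describe 16 female Hos:HR-1 mice assigned to 2 diets, 8 mice per diet and 4 per cage, and the series gives 4 arrays per diet. Which mice and cages the arrays came from, how the mice were chosen for them, and any array batch are not given in the sources used here.

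The authors deposited log2 values in a single table with a column per array. The submitters' processing notes name R 2.7.2. The summary and normalization methods, like the genome build, are not given in the sources used here. The log2 scale was read from the values, which run from 6.56 to 14.46 with nearly the same distribution in each array. Ranges over the arrays were very small and unequal between probe sets, for a cause that is not given in the sources used here, so no difference was converted to a fold change. Whether a probe set's spread on the deposited scale shows its spread in the skin is unknown. No detection calls or scanner values were used, so signal over background is unknown. No pair of arrays held identical values, and each pair shared between 30 and 53 probe sets with equal values.

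Values were used as deposited. The 64 control probe sets were left out, which left 45037. The platform annotation gave 1 gene symbol for 34945 of these, several for 932 and none for 9160. Of the first, 34741 matched the gene table of assembly GRCm38.p6 by Entrez identifier, and 0 symbols changed. That table was used for names and gene neighbourhood only. For each of 18193 genes the single-gene probe set with the highest mean over all 8 arrays was used.

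Probe sets and genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, collagen minus control, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior degrees of freedom were 0.514 for probe sets and 0.488 for genes, so little was borrowed between them. For genes with a very small spread of their own, the prior still raised the SE. Tables were read and written with the R package data.table (version 1.17.8), and figures drawn with matplotlib 3.10.9.

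A set of 47 gene lists (pathways, gene families, cell type markers and housekeeping controls, 865 genes) was fixed before the data were examined, and 771 of these genes were measured. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 47 lists, with at least 5 measured genes. Camera with an estimated correlation and fry were run beside it. When camera estimates a correlation it sets residual variances under 1e-08 to that floor, and 91.6% of genes here lay under it. All values were therefore multiplied by 1e+06 before camera and before the estimation of array weights. The factor is the same for each value and changes no t statistic, and without it those genes enter the estimate with too little weight. A list score is the mean over its genes of the z value in each array, and was compared between diets by an exact permutation test over 70 assignments.

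Named genes followed a rule fixed before the data were examined. They had a probe set with 1 gene symbol and a higher group mean at or above 8.193, the median of all probe set means. The first part took up to 10 genes per direction with the largest difference among those past adjusted p 0.05 without overlap between diets, filled from those at unadjusted p under 0.01 without overlap. The second part took 4 members with the smallest p in each list that passed, and up to 2 in other lists described. The third part was Col1a1, Col1a2, Col3a1, Eln, Has2, Flg, Lor, Ivl, Krt10, Krt14 and Mmp13. H2-Eb1, H2-Aa, H2-Ab1, Cd74, Myh4, S100a8, Abcb6 and the members that lay against their list were named after their values were seen.

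The tests were tested on simulated data. With 200 of 18193 genes changed, limma recovered 2.39%, 27% and 93.3% of genes shifted by 2, 4 and 8 within-group SD, with 4.5 false calls per simulation. In 20 simulations of unchanged lists whose genes shared a correlation of 0.5, camera with the preset correlation called a mean of 18.55 of 47 lists and at most 28, and camera with an estimated correlation called 0. The correlation estimated for the real lists had a median of 0.277, so most were less correlated than the simulated ones. Among the lists called below it ran from 0.14 (matrix proteases) to 0.84 (keratin-associated proteins). In separate simulations whose genes shared no correlation, lists shifted by 1 SD were called in 99.5% of cases with the preset correlation. How often camera with an estimated correlation, fry or the exact test call a shifted list was not simulated. Their counts of 0 lists cannot be read against this recovery.

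Alternatives were each left-out array, quantile normalization, median centring, filters on dim probe sets, variance models, array weights, the replicate number as a block, rank products, an unmoderated equal-variance test, a pseudocount of 16 on the linear scale, a looser threshold of 0.1, other rules for the probe set of a gene, and other list tests. Dividing each gene by its SD, the exact test of list scores, the Gapdh 3' minus 5' difference as a covariate, the muscle list score as a covariate, and leaving out control 1 and collagen 1, the arrays with the lowest weights (0.539 and 0.576), were added after seeing the data.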

Results

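Gene expression was measured in the dorsal skin of female Hos:HR-1 mice, a hairless strain, that were 10 weeks old at sampling. The mice were fed either AIN-93G, a purified rodent diet, or the same diet with fish-scale collagen hydrolysate (collagen cut into short peptides) at 2.0 g per 100 g, for 1 week. The series holds 8 arrays, 4 from control mice and 4 from collagen-fed mice, and the labels call the arrays of each diet biological replicates. Each array gave 45101 probe set values. The medians of the arrays lay between 8.1929 and 8.1932 on the deposited log2 scale, with values from 6.56 to 14.46. The number of arrays limits the precision of every value given here. Unless another n is stated, means and standard errors (SE) rest on n = 4 arrays per diet.

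The deposited values hardly varied between mice. The median probe set had a range of 7.36e-06 over the 8 arrays, the 95th percentile of this range was 4.64e-04, and 87.2% of the 45037 probe sets had a range under 0.0001. Only 31 probe sets had a range over 0.1. These ranges were very small and unequal between probe sets, for a cause that is not given in the sources used here. Whether a difference equals a log2 fold change is unknown, so no fold change is given. Differences are given on the deposited scale with their SE, and as multiples of the within-group SD. The SE of a difference is limma's moderated SE, which for genes of very small spread is larger than their own spread gives.

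**Figure D1:**
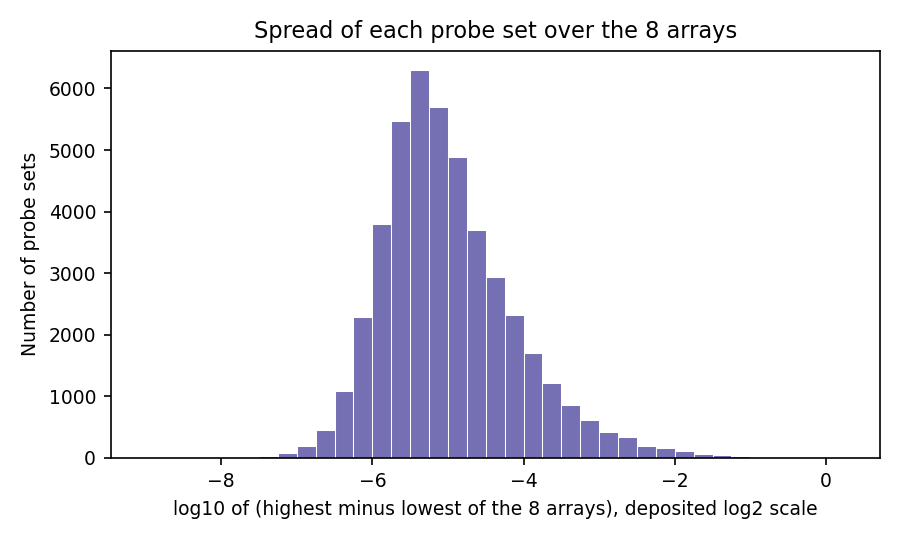
Histogram of the range of each probe set over the 8 arrays (highest minus lowest deposited log2 value, on a log10 axis in bins of 0.25), with the number of probe sets on the vertical axis. The median range was 7.36e-06, and 2 probe sets had a range over 1.

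The comparison asks which genes of dorsal skin differed in level after 1 week of collagen hydrolysate. No single gene was separated from the spread between mice. At adjusted p under 0.05 by limma's moderated test, 0 of 45037 probe sets and 0 of 18193 genes passed, and the smallest adjusted p was 0.586 for probe sets and 0.999 for genes. At unadjusted p under 0.05 there were 1601 probe sets (1013 higher and 588 lower with collagen), where 2250 are expected by chance, and 635 genes (411 higher and 224 lower), where 910 are expected. Rank products, another test, called 696 probe sets, 162 higher and 541 lower with 7 called both ways, and quantile normalization gave 2 probe sets. The values of both diets did not overlap in 368 genes (2.02%), against 2.86% expected by chance. In data simulated at the real means and spreads, 200 genes were changed at once. There the same test recovered 93.3% of genes shifted by 8 within-group SD, 27% of those shifted by 4 and 2.39% of those shifted by 2. The adjustment is stricter when fewer genes change, and such a case was not simulated. This recovery therefore does not show that isolated changes of 8 SD would have been found.

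Of 18193 genes, 117 had an unadjusted p under 0.01 by limma's moderated test, and none of them passed the adjusted test. Those with a higher group mean at or above 8.193, the median of all probe set means, and no overlap between the diets numbered 90. Of these 90 genes, 60 were higher and 30 lower with collagen. The lower ones included Gpnmb, a glycoprotein of melanocytes and macrophages, with a difference of -4.46e-04 ± 4.86e-05 (SE), or -6.24 within-group SD. Mfge8, a secreted protein that bridges dying cells to phagocytes, differed by -2.01e-04 ± 2.52e-05, or -5.42 SD. Wfs1 differed by -2.14e-04 ± 3.80e-05 and Crabp1, a retinoic acid binding protein, by -6.38e-04 ± 1.24e-04. The largest differences of this side were those of Ppp1r27, -0.00551 ± 0.00133, and H2-Ob, -0.00149 ± 3.95e-04. Frzb, a secreted Wnt inhibitor, Camk2a, Igf2 and Slit3 completed the 10 lower genes, with differences from -3.49e-04 (Frzb) to -4.20e-05 (Slit3).

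The 10 higher genes were led by D17H6S56E-5, with 0.0347 ± 0.00906, followed by Cxcl3, a chemokine that attracts neutrophils, with 0.0120 ± 0.00305, and Vps52, with 0.00542 ± 0.00148. The other 7 differed by between 1.74e-05 (Ddx27) and 3.03e-05 (Fgfr2) and were Fgfr2, Srsf10, Dis3, Nasp, Fastkd2, Mak16 and Ddx27. All 20 genes had an adjusted p of 0.999 over all genes.

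Gpnmb was the 1 gene of the 771 measured list genes that passed when adjusted over the list alone. Its adjusted p by limma was 6.54e-04 over the 11 melanocyte and pigment genes and 0.0458 over all 771. The second of these calls was kept without collagen 1 (0.0359). It was lost without each of the other 7 arrays (0.0674 to 0.25) and after median centring (0.225), while the difference stayed between -4.66e-04 and -3.91e-04. After quantile normalization the difference was -1.29e-04 (adjusted p = 1). A second Gpnmb probe set, at a level of 7.60, differed by -2.31e-06 with an unadjusted p of 0.144. In the same list Tyrp1, a melanin synthesis enzyme, lay 0.00359 ± 0.00139 higher. The melanocyte list did not shift one way (8 of 11 genes higher, adjusted p = 0.214 by camera), and it was the 1 list past fry's test for change in either direction (adjusted p = 0.00629). Gpnmb had a t of -9.18 there and Tyrp1 one of 2.59, so that list call may rest on Gpnmb. The list was not tested without Gpnmb.

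Collagen genes lay slightly lower in the collagen-fed mice. Of 16 fibrillar and dermal collagens, 15 were lower and Col18a1 was higher (camera with a preset correlation, adjusted p = 0.00149; adjusted p = 0.747 with an estimated correlation). No member passed on its own. Col5a1 differed by -9.59e-04 ± 5.59e-04, Col1a1 by -0.00288 ± 0.00171, Col15a1 by -1.83e-04 ± 1.21e-04 and Col6a1 by -3.81e-04 ± 2.54e-04. The most abundant of them differed by less than their spread, with -9.83e-06 ± 8.11e-06 for Col1a2 and -2.56e-06 ± 2.24e-06 for Col3a1.

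The enzymes that modify and crosslink collagen were lower in 14 of 18 genes (adjusted p = 0.0133, and adjusted p = 0.747 with an estimated correlation). Loxl1, a crosslinking oxidase, differed by -1.28e-04 ± 5.51e-05, P4ha2, a prolyl hydroxylase subunit, by -5.00e-04 ± 2.23e-04, Pcolce by -2.17e-04 ± 1.11e-04 and Plod1 by -1.69e-04 ± 9.63e-05. Matrix proteases and their inhibitors were lower in 14 of 18 genes (adjusted p = 0.0133, and adjusted p = 0.747 with an estimated correlation), among them the proteases Mmp12 (-2.24e-04 ± 8.71e-05), Mmp13 (-0.00143 ± 7.31e-04) and Mmp2 (-7.85e-05 ± 4.27e-05) and the inhibitor Timp2 (-3.87e-05 ± 2.28e-05). Fibroblast markers were lower in 11 of 13 genes (adjusted p = 0.0133, and adjusted p = 0.747 with an estimated correlation), with Twist2 at -2.65e-05 ± 1.31e-05, Pdgfra at -7.10e-05 ± 3.73e-05 and Thy1 at -0.00113 ± 8.87e-04. The fibroblast list shared 5 of its genes with other lists. All 4 groups had their lowest score in collagen 2 or collagen 1, and collagen 4 scored above the control mean in each. Without collagen 2 the adjusted p was 0.0875 for the collagens, 0.22 for the enzymes, 0.181 for the proteases and 0.334 for the fibroblast markers. Without control 1 it was 0.0600 for the collagens and 0.0626 for both the proteases and the fibroblast markers. The collagens also lost the call without collagen 1 (0.117), the enzymes without control 2 (0.113), and the fibroblast markers without control 3 (0.0845) and collagen 1 (0.0792). All 4 calls were lost after quantile normalization and with the Gapdh 3' minus 5' difference as a covariate (0.0693 to 0.112). With that covariate the mean t moved from -0.972 to -0.709 for the collagens and from -0.783 to -0.605 for the enzymes. For the proteases it moved from -0.774 to -0.698, and for the fibroblast markers from -0.848 to -0.64. This Gapdh difference is not specific to RNA quality, as described further below.

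Skeletal muscle genes lay lower in the collagen group. Of 24 markers of skeletal muscle, which lies beneath mouse dorsal skin, 23 were lower and Myh4, a fast myosin heavy chain, was higher (adjusted p = 3.85e-06 by camera; adjusted p = 0.747 with an estimated correlation). Casq1, a calcium store protein, differed by -0.00284 ± 0.00114, Eno3 by -4.44e-04 ± 2.05e-04, Myh2 by -0.0323 ± 0.0155 and Mylpf by -3.00e-04 ± 1.54e-04. Myh4 differed by 0.204 ± 0.255, or 0.545 within-group SD, a larger difference on the deposited scale than any of these. All 23 oxidative phosphorylation genes were lower (adjusted p = 3.87e-04; adjusted p = 0.747 with an estimated correlation), with -6.80e-06 ± 3.14e-06 for Sdhb, -4.05e-05 ± 1.96e-05 for Sdhc, -4.79e-06 ± 2.46e-06 for Ndufv1 and -7.10e-07 ± 4.07e-07 for Cox6c. Both lists had their highest score in control 4 (1.24 and 1.31) and their lowest in collagen 1 (-1.42 and -1.27). The muscle call was kept without each array in turn, and ended with the same Gapdh covariate (mean t from -1.21 to -0.414, adjusted p = 0.144), as did that of oxidative phosphorylation (-0.185, adjusted p = 0.491). The oxidative phosphorylation call was also lost without control 4 (adjusted p = 0.0770) and after both scalings. After median centring, which raised the mean t of all genes to 0.610, the list lay at 0.636 (adjusted p = 0.851). With the muscle score as a covariate, the mean t of the oxidative phosphorylation list was 0.0524, against -0.928 without it.

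Cholesterol synthesis genes lay higher with collagen, in 18 of 18 genes measured (adjusted p = 4.42e-05; adjusted p = 0.747 with an estimated correlation). Insig1, a regulator of sterol sensing, differed by 2.28e-04 ± 1.14e-04, and the enzymes Fdft1, Cyp51 and Fdps by 1.48e-04 ± 7.49e-05, 5.20e-04 ± 2.78e-04 and 1.55e-04 ± 8.30e-05. Their score was highest in collagen 2 (1.62), and collagen 4 (-0.669) lay below 3 of the control arrays. Cell cycle genes were higher in 20 of 27 (adjusted p = 0.0133; adjusted p = 0.747 with an estimated correlation). Among members at or above the level of 8.193, those with the smallest p were the DNA replication genes Mcm4 at 4.65e-06 ± 1.35e-06, Mcm5 at 8.35e-06 ± 2.45e-06, Rrm1 at 2.34e-05 ± 7.89e-06 and Mcm6 at 1.50e-05 ± 6.53e-06. The 7 lower members (Aurka, Aurkb, Bub1b, Ccnb2, Cenpa, Plk1 and Tpx2) did not pass on their own, like the 20 higher ones. The cholesterol call was kept without each array in turn and lost after quantile normalization. The cell cycle call was lost after both scalings and without collagen 2 (0.437), control 1 (0.225), collagen 4 (0.114) and control 4 (0.0601).

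Interferon response genes were lower with collagen in 19 of 19 (adjusted p = 1.17e-04; adjusted p = 0.747 with an estimated correlation), and the call was kept without each array in turn. It ended with the Gapdh difference as a covariate (mean t from -1.07 to -0.378, adjusted p = 0.212). The differences were -9.26e-04 ± 5.59e-04 for Irgm1, -5.39e-04 ± 3.66e-04 for Psmb8, -4.63e-04 ± 3.38e-04 for Gbp3 and -0.00512 ± 0.00378 for Oasl2. Their score ran from -1.3 (collagen 1) to 0.915 (collagen 4) within the collagen group and from -0.586 to 1.27 within the control group. With the muscle score as a covariate their mean t was -0.394 (adjusted p = 0.224), against -1.07 without it. Macrophage and dendritic cell markers were lower in 14 of 21 genes (adjusted p = 0.0376; adjusted p = 0.855 with an estimated correlation). Cd207, the langerin of Langerhans cells, differed by -2.40e-05 ± 6.94e-06 and Itgax by -1.51e-04 ± 4.72e-05, while H2-Eb1, a class II antigen presentation gene, and Lyz1 lay higher, by 0.625 ± 0.207 and 1.06e-06 ± 4.57e-07. With 1 array left out, that call was kept only without collagen 3 (0.0329) and without collagen 4 (2.64e-04), with 0.0600 to 0.601 without each of the other arrays, and was lost after quantile normalization and with the Gapdh covariate (0.212). The mean t of this list was -0.426 with the Gapdh covariate, against -0.589 without it. Endothelial markers were lower in 13 of 15 genes (adjusted p = 0.0133; adjusted p = 0.747 with an estimated correlation), with Cdh5 at -2.51e-05 ± 1.05e-05, Kdr at -5.88e-05 ± 3.84e-05, Esam at -1.99e-06 ± 1.38e-06 and Vwf at -5.42e-05 ± 3.81e-05. Their call was lost without collagen 2 (0.311) and control 4 (0.0652), after quantile normalization and with the Gapdh covariate (0.110). With that covariate the endothelial mean t was -0.605, against -0.783 without it. After median centring the call was also lost (0.0810), with a mean t of 0.363 that lay below the 0.610 of all genes.

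H2-Eb1 had a wide range over the arrays and was chosen after its values were seen. Control 1, 2 and 3 lay at 9.32, 9.35 and 9.35, control 4 at 10.18, and the collagen arrays between 10.05 and 10.28, so that control 4 lay within the collagen range. The dimmest of 4 H2-Aa probe sets, chosen after its values were seen (8.04 to 8.05 in control 1 to 3, 8.11 in control 4 and 8.11 to 8.15 with collagen) and D17H6S56E-5 (9.02 in control 1 to 3, 9.06 in control 4 and 9.06 to 9.08 with collagen) likewise had control 4 near the collagen arrays. So did Vps52, with 8.836 to 8.837 in control 1 to 3, 8.841 in control 4 and 8.842 to 8.846 with collagen. Its split was also seen only after its values were looked at. The brightest H2-Aa probe set, the one used for the gene, differed by 2.01e-05 ± 5.80e-05, and the second brightest by -0.00120. The fourth differed by 0.00371 (unadjusted p = 0.0246) and had the split too, with 10.837 to 10.838 in control 1 to 3, 10.841 in control 4 and 10.840 to 10.844 with collagen. Cd74, the class II invariant chain, differed by -5.43e-04 ± 2.72e-04, and H2-Ab1 by -1.68e-04 ± 1.20e-04.

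**Figure D2:**
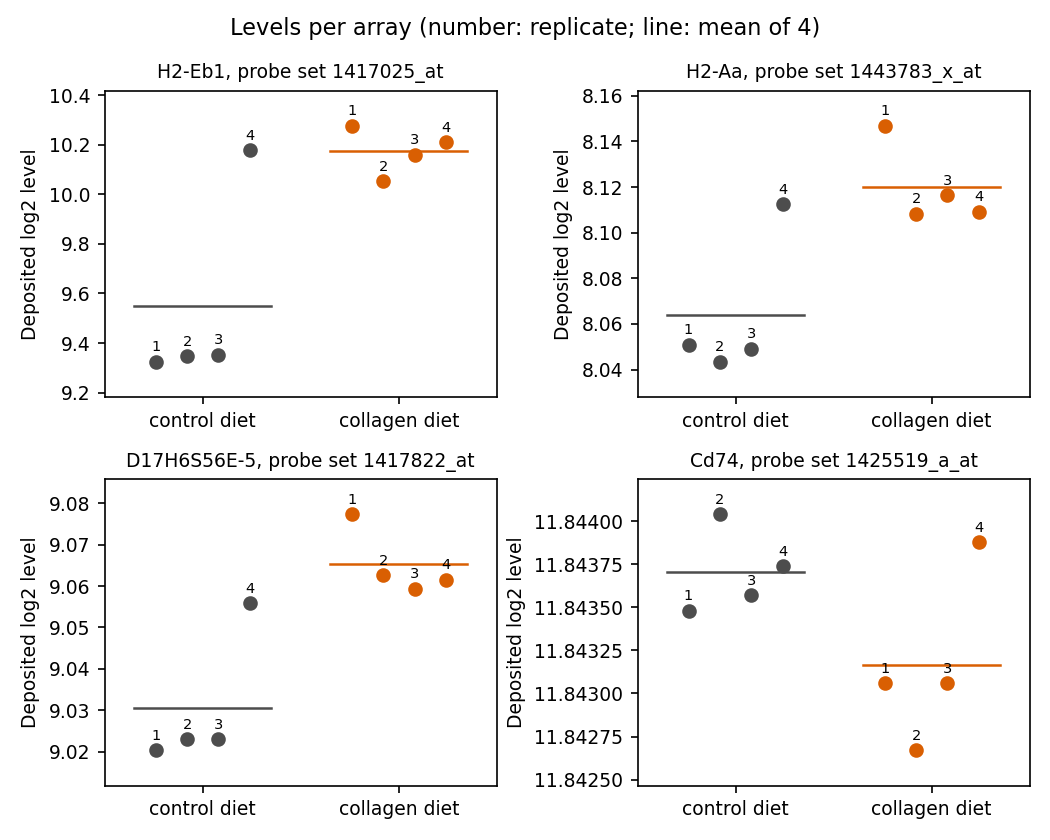
Deposited log2 levels of H2-Eb1, the dimmest of 4 H2-Aa probe sets (chosen after its values were seen), D17H6S56E-5 and Cd74 in each array, by diet, with the replicate number at each point, a line at the mean of the 4 arrays, and a vertical axis of its own for each gene that does not start at 0. For H2-Eb1, control 4 (10.18) lies among the collagen arrays (10.05 to 10.28) and apart from control 1 to 3 (9.32 to 9.35).

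Hair follicle genes varied widely between mice on the same diet. Inner root sheath and companion layer genes were lower with collagen in 13 of 15 (adjusted p = 0.0133; adjusted p = 0.752 with an estimated correlation), with Ctsc at -2.37e-05 ± 1.19e-05, Krt72 at -3.26e-04 ± 2.51e-04, Krt26 at -0.00365 ± 0.00297 and Padi3 at -0.00319 ± 0.00306. Keratin-associated proteins, the matrix proteins of the hair shaft, were lower in 21 of 33 (adjusted p = 0.0133; adjusted p = 0.855 with an estimated correlation), with Krtap7-1 at -0.0427 ± 0.0275, Krtap15 at -0.0758 ± 0.0547, Krtap8-1 at -0.0553 ± 0.0452 and Krtap4-6 at -0.0247 ± 0.0214. The lowest and the highest scores of the keratin-associated proteins were both in collagen-fed mice, -1 in collagen 1 and 1.66 in collagen 3. Without collagen 4, collagen 1, and control 1 their adjusted p was 0.528, 0.389 and 0.404, and without collagen 2 it was 0.181. The inner root sheath call was lost without collagen 1 (0.389), control 1 (0.189), control 2 (0.164) and collagen 4 (0.138). Array weights turned both signs. The mean t of the inner root sheath list was then 0.107 (adjusted p = 0.857 by camera). For the keratin-associated proteins it was 0.692, and they passed with that opposite sign (adjusted p = 0.0448). With the muscle score as a covariate the mean t of these 2 lists was -0.244 (adjusted p = 0.534) and -0.189 (adjusted p = 0.468), against -0.769 and -0.531 without it. Both calls ended with the Gapdh covariate too (0.222 and 0.110), where the mean t was -0.421 and -0.406.

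**Figure D3:**
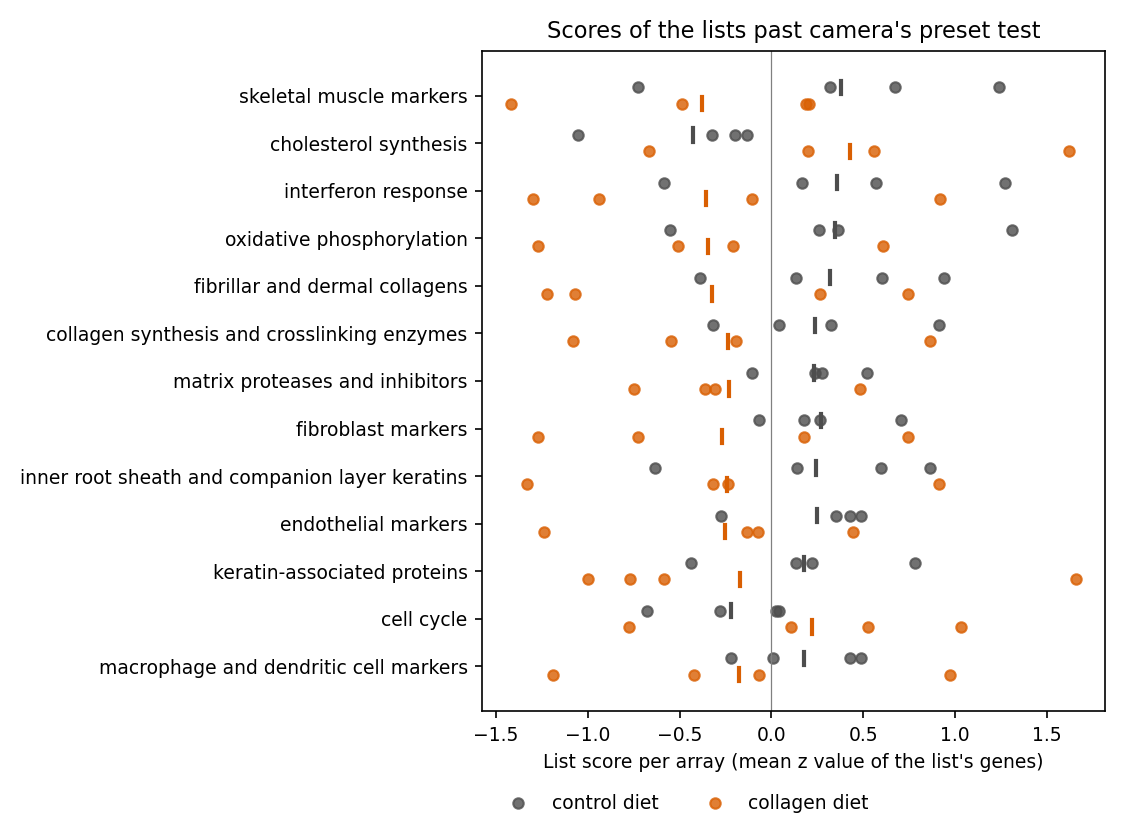
Score of each of the 13 lists past camera's preset test, 1 point per array, by diet (horizontal axis: mean of the members' z values over the 8 arrays), with a short line at the mean of the 4 arrays of a diet. The diets overlap in each list, and the keratin-associated proteins run from -1 to 1.66 within the collagen-fed mice.

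In all, 13 of 47 lists fixed before the data were examined passed camera with a preset correlation of 0.01, 2 higher and 11 lower with collagen. After quantile normalization 0 lists passed as higher and 4 as lower, all among the 13. After median centring 1 passed as higher and 17 as lower, of which 10 were among the 13 and 8 were not. The 8 were elastic fibre, proteoglycans, basement membrane, hair keratins, immediate early genes, adipocytes, brown adipocytes, and B and plasma cells. Their adjusted p ran from 3.31e-09 (hair keratins) to 0.0397 (adipocytes). Centring gave most genes nearly the same offset, so calls there are no separate support. The 4 kept after quantile normalization were skeletal muscle, interferon response, inner root sheath and keratin-associated proteins, so the cholesterol call ended there, and centring ended those of oxidative phosphorylation, endothelial markers and cell cycle. With the correlation estimated from the arrays (median 0.277 over the lists), 0 lists passed and 0 had an unadjusted p under 0.05. Fry passed 0 lists in its directional test. The exact permutation test of list scores over 70 assignments, whose smallest possible two-sided p is 0.0286, gave a smallest p of 0.0857. Leaving out an array gave between 5 lists (without collagen 2) and 18 (without collagen 4), and without control 1 there were 6. Without control 1 and collagen 1 together there were 9, of which 6 were among the 13. The 3' minus 5' difference of Gapdh was 0.290410 in control 1 and 0.290578 in collagen 1, and 0.289775 to 0.290112 in the other 6 arrays (exact permutation p = 0.343 between the diets, two-sided). Collagen 1 and control 1 had the lowest muscle and oxidative phosphorylation scores of their diets, and the lowest interferon scores. With this Gapdh difference as a covariate 3 lists passed, all higher with collagen: cell cycle (4.53e-07), cholesterol synthesis (3.11e-04) and oxidative stress response (0.0281). The 11 lower calls ended. Their mean t moved most for skeletal muscle (-1.21 to -0.414), oxidative phosphorylation (-0.928 to -0.185) and interferon response (-1.07 to -0.378). It moved less for the others, such as the collagens (-0.972 to -0.709) and inner root sheath (-0.769 to -0.421). A lost call is thus not always a lost shift.

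Epidermal genes did not pass as groups. Suprabasal and cornified envelope genes were higher in 25 of 39 (adjusted p = 0.59 by camera, as for the lists that follow), and Flg (filaggrin), Lor (loricrin) and Krt10 differed by less than the within-group SD, with -9.85e-06 ± 1.84e-04, -5.30e-07 ± 4.10e-06 and 2.83e-07 ± 4.09e-07. Ivl (involucrin) differed by 4.16e-04 ± 2.29e-04, or 1.24 SD, and Krt14 by 2.35e-07 ± 2.33e-07, or 1.87 SD, with no overlap between the diets for Krt14. None of these 5 passed. The moderated SE of Krt14 was larger than its SD in either diet (6.68e-08 in control and 1.65e-07 in collagen arrays). Cdsn differed by -5.00e-04 ± 2.34e-04. Basal keratinocyte markers were higher in 8 of 12 (0.191), with Trp63 at 6.21e-05 ± 2.59e-05 and Itgb4 at -5.23e-06 ± 2.04e-06. Hyperproliferation keratins and alarmins were higher in 12 of 15 (0.133), with Krt6b at 0.0180 ± 0.00532 and Krt16 at 1.37e-04 ± 5.46e-05. Barrier lipid synthesis genes were higher in 20 of 24 (0.122), cell junction genes in 15 of 21 (0.517), and genes of natural moisturising factor, water and glycerol in 4 of 12 (0.71).

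Other dermal groups did not pass either. Elastic fibre genes were lower in 9 of 14 (adjusted p = 0.0710 by camera, as for the lists that follow), with Eln, the elastin gene, at -3.71e-05 ± 2.26e-05. Proteoglycan and hyaluronan genes were higher in 10 of 17 (0.615; lower than other genes after median centring, 0.0331), with Has2, a hyaluronan synthase, at -1.27e-04 ± 1.83e-04. Basement membrane genes were lower in 10 of 15 (0.122) and TGF-beta response genes in 10 of 15 (0.499). Genes of peptide and amino acid transport and proline metabolism were lower in 13 of 21 (0.101), with the peptide transporter Slc15a3 at -1.97e-05 ± 4.95e-06. After median centring, elastic fibre (6.26e-08) and basement membrane genes (2.49e-04) also passed as lower than other genes. That scaling gave most genes nearly the same offset, so these calls add little.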

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

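The tests over other splits of the arrays, both simulations for rank products, the Gapdh covariate and both tests of the H2-Eb1 pattern were chosen after the result was seen; the division by the SD and the muscle covariate were set before their results. A value was listed when 1 array of a diet lay far from the other 3 (the gap to the nearest of them, divided by the range, above Dixon's critical value). Of 402 groups of 4 arrays examined, 20 were listed, and chance lists about 1 in 20 groups, or 20.1.

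Among list scores, control 2 lay above the other controls for basal keratinocyte markers (ratio 0.85) and collagen 3 above the other collagen arrays for keratin-associated proteins (0.843). Control 4 was apart from the other controls for H2-Eb1 (0.967, higher), D17H6S56E-5 (0.926, higher), Cdsn (0.914, lower), Frzb (0.877, lower) and Col1a2 (0.856, lower). Control 1 was apart for Atp1b1 (0.935, higher), S100a8 (0.908, higher), Ppargc1a (0.907, higher), Cox6c (0.892, lower) and Ltbp3 (0.867, higher). In the collagen group, collagen 1 was apart for Gpnmb (0.939, lower) and Vps52 (0.903, higher), collagen 2 for Krt16 (0.897, higher), Fgfr2 (0.863, lower), Myh4 (0.862, lower) and Krt14 (0.833, higher), collagen 3 for Jun (0.898, lower), and collagen 4 for Slc15a3 (0.907, higher).

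H2-Eb1 split the control arrays, with control 4 at 10.18 against 9.32 to 9.35 in the other 3. More antigen-presenting cells in control 4 are argued against by the other 20 measured genes of the macrophage and dendritic cell list, of which 2 (H2-Aa and Lyz1) had control 4 above the other controls; by probe set this held for 4 of 4 of H2-Aa and 0 of 4 of Cd74 and H2-Ab1. A sequence difference between mice in the H2 region, the mouse MHC, stays open as a hypothesis: among 176 probe sets of the 50 genes on either side in the gene order of assembly GRCm38.p6, 4 shared the H2-Eb1 profile (2.27%; root mean square difference of z values up to 0.3, either sign), against 4 of 34705 elsewhere (0.0115%; one-sided Fisher's exact p = 4.32e-08). These 4 belonged to D17H6S56E-5, H2-Aa and Rps28, some had been seen to share the profile before the test, the probe sets are not independent, and an unequal share of such mice between the diets could give differences of these genes that diet did not make; diet stays open, as untested here.

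Skeletal muscle and oxidative phosphorylation genes lay lower together in the collagen group, where 1 of the 24 muscle genes (Des) is also in another list and Acta1, Tnnc2 and Myh1 were the most abundant, at 13.99, 13.68 and 13.33. Unequal amounts of underlying muscle in the skin pieces may explain the oxidative phosphorylation shift: with the muscle score as a covariate its mean t moved from -0.928 to 0.0524. That covariate was not specific to muscle energy genes, as it also moved interferon response (-1.07 to -0.394), inner root sheath (-0.769 to -0.244), keratin-associated proteins (-0.531 to -0.189) and hair keratins (-0.573 to 0.00741), while collagens (-0.972 to -0.803), fibroblast markers (-0.848 to -0.819) and cholesterol synthesis (1.36 to 1.5) moved less. A difference in RNA quality between arrays cannot be told apart from a difference in muscle. With the Gapdh 3' minus 5' difference as a covariate the mean t of the muscle list moved from -1.21 to -0.414, between the bounds set for it as the cause and against it. The Gapdh difference is not specific to RNA quality. The Gapdh 5' level was lowest in collagen 1 (12.9911) and control 1 (12.9913) and highest in control 4 (12.9922), as was the muscle score. The Actb 3' minus 5' difference did not set control 1 apart (0.38005, and 0.380049 to 0.380051 in the other arrays). Diet stays open as an untested explanation, and the exact permutation p of the muscle score was 0.229.

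Rank products called 696 probe sets where limma called 0. A spread that differs between probe sets may explain these calls, since simulated values with no change at the real means and spreads gave 655, and the called probe sets had a median range of 0.00618 against 7.36e-06 for all. Dividing each probe set by its SD left 0 calls, which decides nothing, since on simulated values the same step recovered 0% of 200 probe sets shifted by 8 SD. Of 35 splits of the 8 arrays, 17 gave as many calls, so chance is not excluded for this count. The highest other split gave 1995. That split parted control 1 and collagen 1 to 3 from the other 4 arrays. Control 1 and collagen 1 to 3 were the arrays below 0 on the first principal component, the main axis of variation between arrays. By limma this split also had the most genes at unadjusted p under 0.05, 3040 against 635 for the diets. A split along the main axis of these same values tends to give many differences, so these facts are not separate support for a structure of the samples. What sets those arrays apart was not tested.

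For the 13 lists past camera's preset test, 19 of 35 splits gave as many and the highest other split gave 23, so chance is not excluded. For the 0 probe sets and the 0 genes, 35 of 35 splits gave as many, which holds for any count of 0 and says nothing about chance; the highest other split gave 2 probe sets and 1 gene.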

How the results depend on the processing

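The exact test of list scores, division by the SD, the Gapdh and muscle covariates, the removal of control 1 and collagen 1 together, and the left-out arrays and scalings for Gpnmb were chosen after seeing the data. The count of 0 genes became 1 with the muscle covariate (Abcb6, higher, adjusted p = 0.0371, and 0.613 to 1 in the others) and stayed at 0 in the other alternatives. The count of 0 probe sets became 2 with quantile normalization (Nrp1 lower and Cep97 higher, with main unadjusted p of 0.0905 and 0.736) and 696 with rank products, and stayed at 0 in the other alternatives. The 13 lists became 4 with quantile normalization, 4 with the replicate block, 0 with an estimated correlation, 0 with fry, 0 with the exact test, 3 with the Gapdh covariate and 9 with the muscle covariate (6 of them among the 13), and 5 to 18 when 1 array was left out. The estimated correlation and the scores take account of genes that vary together between mice, which the preset test does not. The exact test could hardly pass a list after adjustment over 47 lists, as its smallest possible two-sided p is 0.0286. Its count of 0 therefore decides little. The cause was not tested for the other changes. Of the 13 lists, skeletal muscle and interferon response were the 2 that passed in each left-out array, both scalings and the block. Passing after median centring is no separate support. The array medians that it removed ran from 8.1929 to 8.1932, while 87.2% of probe sets had a range under 0.0001. Most genes therefore took nearly the same offset. Over the alternatives, the highest adjusted p of each of the 13 lay between 0.875 and 0.967. Median centring raised the mean t of all genes to 0.610, and with it those of basement membrane (0.137), adipocyte markers (0.312), endothelial markers (0.363), immediate early genes (0.198) and oxidative phosphorylation (0.636) to above 0. The first 4 stayed below other genes in camera, so these signs follow from the common shift. Array weights turned inner root sheath (0.107) and keratin-associated proteins (0.692, which passed with that sign, adjusted p = 0.0448 by camera). The muscle covariate turned oxidative phosphorylation (0.0524). Leaving out control 1 and collagen 1 turned keratin-associated proteins (0.117, adjusted p = 0.9205 by camera) and mast cell markers (-1.146). The mast cell markers passed with that sign (adjusted p = 0.01105). The cause was not tested for these last 5. Collagen 3 had the highest array weight (2.29) and the highest score of inner root sheath (0.912) and keratin-associated proteins (1.66). For keratin-associated proteins control 1 scored highest of the controls (0.782) and collagen 1 lowest of the collagen arrays (-1). For mast cell markers control 1 scored lowest of the controls (-1.09) and collagen 1 highest of the collagen arrays (1.69). Median centring moved the median difference of all genes by 5.52e-05 and quantile normalization by 5.97e-06, small on a log2 scale but as large as many differences named here. Of 153 named genes, Abcb6 was the 1 that passed under any alternative. It was named after that result was seen, and no other named gene passed. Of the 153, 66 changed sign in at least 1 alternative, which a common shift can give. Without the 2 scalings 17 did. Same-numbered arrays of both diets deviated together with correlations of 0.369, 0.0531, 0.22 and 0.0187, and replicates 1 and 3 but not 2 and 4 correlated best with their own number. They share only a number, and the replicate block gave 0 genes, 0 probe sets and 4 lists. Signal over background is unknown, and sets no limit that could be tested.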

Other observations

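The values in this part were not chosen by a test, and the array controls were looked at after the main results. Further groups fixed before the data were examined did not pass camera's preset test. Oxidative stress response genes were higher with collagen in 16 of 19 (adjusted p = 0.053), with Gclc and Srxn1, genes of glutathione synthesis and thiol repair, at 1.95e-05 ± 8.95e-06 and 2.39e-05 ± 1.12e-05. Circadian clock genes were higher in 11 of 18 (0.224), with Per2 at 6.50e-04 ± 2.08e-04 and Cry1 at 2.92e-04 ± 1.11e-04. Heat shock and unfolded protein response genes were higher in 12 of 20 (0.214), ribosomal protein genes in 12 of 14 (0.821), and immediate early genes in 12 of 21 (0.573), where the median t (0.0518) was above 0 while the mean t (-0.114) and camera pointed lower. Fatty acid synthesis genes were higher in 11 of 18 (0.875) and fatty acid oxidation genes lower in 11 of 17 (0.214). Hair keratins were lower in 9 of 12 (0.103), hair follicle growth regulators in 17 of 27 (0.489), and Wnt targets and inhibitors higher in 9 of 17 (0.866). Inflammatory cytokines and chemokines were higher in 19 of 29 (0.653). Housekeeping genes were lower in 6 of 10 (0.252).

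Among cell types, B and plasma cell markers were lower in 5 of 8 (adjusted p = 0.0710), with Igha at -0.00522 ± 0.00276 and Jchain at -0.00592 ± 0.00341, and T and NK cell markers in 11 of 16 (0.499). Mast cell markers were higher in 8 of 10 (0.489) and neutrophil markers in 9 of 11 (0.653). Without control 1 and collagen 1 the mast cell list turned to a mean t of -1.146 and passed camera (adjusted p = 0.01105). Adipocyte markers were lower in 9 of 14 (0.341), brown adipocyte markers in 5 of 10 (0.422), and nerve and Schwann cell markers in 5 of 9 (0.74). Sebaceous gland markers were higher in 10 of 14 (0.543). Erythrocyte markers were higher in 3 of 6 (0.499), where the mean t (-0.325), the median t (-0.508) and camera pointed lower. Smooth muscle and pericyte markers were higher in 6 of 12 (0.543), with a median t of 0.0826 while the mean t (-0.215) and camera pointed lower.

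A control probe set for the middle of 18S ribosomal RNA lay at 11.004 in control 3 and between 11.13 and 11.19 in the other 7 arrays. The 3' minus 5' difference of Actb had a mean of 0.380049 in control and 0.380050 in collagen arrays (difference 3.05e-07, exact permutation p = 0.600, two-sided). The first principal component held 26.9% of the variance, with collagen 1 (-126.0) and control 1 (-64.9) at its low end, and an exact permutation p of 0.314 between the diets.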
